A study of Rattus norvegicus with 16 samples.

How the data were processed

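Liver RNA of male Sprague-Dawley rat pups aged 21 days was measured on 16 dual-colour Agilent arrays on 2 slides, 8 arrays to a slide. Per the labels there were 4 groups of 4 arrays, and the RNA of 2 pups of a treatment group was pooled for each array. Cy5 carried the liver RNA and Cy3 a universal rat reference RNA on every array, with no dye swap. The other groups and the adult age of the study were not analysed here. The labels do not say which litter a pool came from, so litter was not modelled.

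Per the file headers, the authors scanned the slides with Agilent Feature Extraction 11.0.1.1, and the deposited scanner files give the median pixel intensity of each spot and of its local background in both channels. They also hold a log10 ratio of Cy5 over Cy3, which per the file headers was made by the scanner software after background subtraction and dye normalization. The deposited series table holds log2 ratios of Cy5 over Cy3 for 30367 probes, centred at medians from -0.049 to -0.037 per array. Its normalization is not stated. Against the ratios computed here its correlation was 0.996 to 0.997 per array and its slope 0.997 to 1.009. The plan assumed mean spot signals, but the files hold only medians, so the median signals were used.

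Each array had 62976 spots, of which 4259 were control spots. Background was corrected with normexp at an offset of 50, spots called outliers by the scanner software were left out, and log2 ratios were normalized within each array by loess with control spots at weight 0. No scaling between arrays was applied. Replicate spots of a probe were averaged. A probe was kept where its Cy5 signal was well above background on at least 3 of the 4 arrays of at least 1 group, which left 13262 of 30367 probes. Probes were named by matching their RefSeq identifiers to a table of the GRCr8 assembly. That gave a symbol to 18005 probes, and the other 12362 kept their own identifier. The probe annotation in the files is of build rn4, and no coordinates were used. The probe with the highest mean signal stood for each gene, so 12072 genes or identifiers were tested, 7895 of them with a symbol. There were 1091 genes with more than 1 kept probe.

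Across arrays the median Cy5 intensity was 87 to 102 over a median background of 67 to 73, and the median Cy3 intensity was 130 to 150 over 20 to 26. Cy5 was well above background at 46.2% to 53.9% of spots. Outlier spots made up 1.32% to 1.85%, and no spot was saturated. The number of arrays limits the precision. The limma 95% confidence interval lay within 2-fold of no change for 98.7% of genes in the comparison of cross-fostered and own-dam controls.

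A model with a mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated statistics from eBayes (12 residual and 3.95 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes of a comparison. Files were read with the data.table package (version 1.17.8) and jsonlite 2.0.0. A gene was called at an adjusted p below 0.05. All tests were two-sided. The comparisons were cross-fostered against own-dam pups without and with the mixture, mixture against control pups without and with cross-fostering, the interaction, and the cross-fostering effect averaged over exposure. The pipeline was tested on simulated data: with 2-fold changes added to 67 genes, 94% to 100% were recovered in the 5 comparisons other than the interaction, and 85.1% in the interaction. With 1.5-fold changes 68.7% to 85.1% were recovered in those 5 and 55.2% in the interaction. The simulation drew independent normal noise for each gene and array. It held no slide shift, array row, aberrant array or correlation between genes, so these rates may overstate the recovery on the real arrays.

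There were 38 gene lists with 787 members named in all, of which 567 were tested. Each list was tested in each of the 6 comparisons with limma's camera at a preset correlation between genes of 0.01, and adjusted over the 228 tests. Camera with an estimated correlation and fry were the alternatives. Fry asks whether the genes of a list move, on balance, in one direction and does not compare them with other genes. Members were also counted when adjusted over the list alone. Some genes are members of several lists.

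The groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names the 10 largest rises and 10 largest falls among called genes whose 4 arrays of one group all lie apart from the 4 of the other and that have an established symbol. Where fewer than 10 genes were called, it names the 10 with the smallest unadjusted p and says that they did not pass. It adds up to 4 members with the smallest p of each list that has a camera call or a called member, and sentinel genes in every comparison. Among the sentinels, Cyp2b1 had no probe in the naming table, and the probes of Nr3c1 and Per1 were too dim to be kept. A few genes that the rule names are not reported here.

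The alternatives chosen beforehand were no background correction, the scanner software's log ratio, the series table, median centring in place of loess, Cy5 alone after quantile normalization, no filter on dim probes, a filter on all 16 arrays, every probe by itself, eBayes with trend and robust settings, only the groups compared, the array row as a block, a fold of at least 1.5 beside the adjusted p, outlier spots kept, the replicate number as a block, and leaving out each array in turn. Alternatives chosen after seeing the data were calls required in both the ratio and Cy5 alone, the array row within each slide as a block, leaving out several arrays at once, and separate fits within each array row. Where a probe was well above background on no array of a group, a fold is given as a bound, with that group set on each array at the lowest Cy5 signal that counted as well above background, or at its own signal where that was higher. The bound uses Cy5 after loess and Aquantile normalization and is open to dye bias without a dye swap. It holds for that scaling only: Cy5 alone after quantile normalization gave folds below most of the bounds given, such as 2.22-fold for Cyp2a3 in M against C against a bound of 2.77.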

Results

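The data were liver expression profiles of male rat pups at 21 days of age, with 4 arrays in each of 4 groups and 2 pups pooled per array. Control pups (C) stayed with their own dams, which received corn oil. Cross-fostered control pups (CC) were raised by other control dams. Mixture pups (M) stayed with dams given a mixture of organochlorine pesticides, polychlorinated biphenyls and methylmercury at 1 mg per kg per day through gestation and lactation, and cross-fostered mixture pups (MM) were raised by other dams given the mixture. All C and CC arrays lay on slide 1 and all M and MM arrays on slide 2, so the slide and the mixture could not be told apart by design, while both cross-fostering comparisons lay within a slide. On each slide, 4 arrays were in row 1 and 4 in row 2, with 2 arrays of each group in each row. The lowest correlation of an array with another of its group was 0.968 to 0.985. The first principal component held 35.1% of the variance and separated the slides, and the second held 18.9% and separated the array rows on both slides, with row 1 at -1.3 to 22.1 and row 2 at -9.4 to -7.9 on slide 1, and row 1 at 4.7 to 15.5 and row 2 at -18.9 to -4 on slide 2.

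The comparison of M with C asks what the mixture changed in pups kept with their own dams. Cyp1a1, the classic target of the aryl hydrocarbon receptor (AhR) in liver, was 39.1-fold higher in M than in C (log2 5.29 ± 0.27 SE, n = 4 arrays per group, adjusted p = 3.43e-09). The adhesion gene Ceacam4 was 9.92-fold higher (log2 3.31 ± 0.12, adjusted p = 2.79e-11). Cyp2b2, the phenobarbital-type target of the constitutive androstane receptor (CAR), was 6.76-fold higher (log2 2.76 ± 0.20, adjusted p = 4.29e-07), and the retinoid-metabolising Cyp2c7 5.08-fold higher (log2 2.34 ± 0.27, adjusted p = 2.44e-05). Cyp1a1 was well above background on 3 of the 4 C arrays. In the Cy5 channel alone, which holds the liver RNA without the reference, these genes were 18.1-fold, 9.71-fold, 11.7-fold and 15.8-fold higher in the same order. Their reference signal, which holds no pup RNA, was also higher on slide 2, by 0.04, 0.36, 0.75 and 1.35 on the log2 scale. A change in Cy5 alone is therefore not free of the slide. Within array row 1 the log2 differences of the ratio were 5.47, 3.34, 2.71 and 2.80, and within row 2 they were 5.10, 3.28, 2.80 and 1.89.

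Among the other largest rises in M were Tsku, a hepatokine gene, at log2 1.83 ± 0.26, the xenobiotic hydroxylase Cyp2a3 at 1.79 ± 0.28 (at least 2.77-fold by the scaling of the bound, but 2.22-fold in Cy5 alone), the retinal dehydrogenase Aldh1a1 at 1.69 ± 0.26, the epoxide hydrolase Ephx1 at 1.65 ± 0.17 and the AhR target Cyp1b1 at 1.52 ± 0.12 (at least 1.93-fold by that scaling, but 1.85-fold in Cy5 alone). All 5 were also called higher in Cy5 alone, with log2 differences of 1.76, 1.15, 1.82, 1.39 and 0.89. The kinesin gene Kif1c was higher in the ratio, at 1.58 ± 0.11, but lower in Cy5 alone, at -0.79, and its reference signal differed by -2.30 on the log2 scale between slide 2 and slide 1. The largest falls in M were in the RNA-binding gene Zc3h13 at -1.45 ± 0.11, the aldo-keto reductase Akr1c13 at -1.15 ± 0.28, the apolipoprotein Apoc2 at -1.05 ± 0.20, the sulfhydryl oxidase Qsox1 at -1.01 ± 0.22, Rabgap1 at -1.0 ± 0.20, Tmem33 at -0.99 ± 0.074, Psd at -0.98 ± 0.12, Mmd2 at -0.98 ± 0.25, Bax at -0.97 ± 0.059 and Tubgcp3 at -0.97 ± 0.093. Of these 10, only Qsox1 was also called lower in Cy5 alone, at -0.99, and another probe for Qsox1 gave -0.15 in the ratio. In Cy5 alone Akr1c13 was at -0.84 and Mmd2 at -0.90 without a call, Zc3h13, Apoc2, Rabgap1 and Psd were at -0.25, -0.07, -0.13 and -0.20, and Tmem33, Bax and Tubgcp3 turned to 0.18, 0.12 and 0.09.

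**Figure D1:**
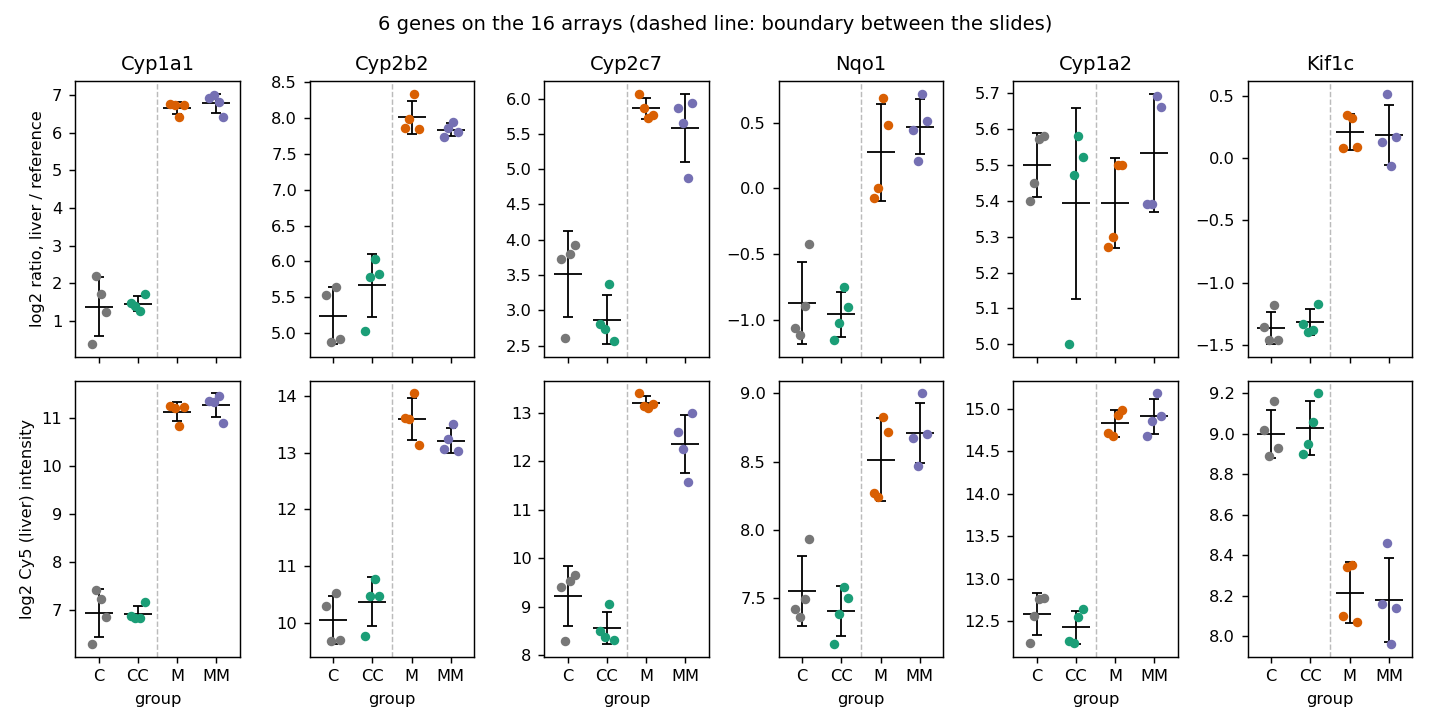
Log2 ratio of liver over reference (top) and log2 Cy5 intensity of the liver channel (bottom) for 6 genes, with a point for each of the 4 arrays per group, bars for the mean ± SD and a dashed line between the slides. Cyp1a1, Cyp2b2, Cyp2c7 and Nqo1 were higher in M and MM in both measures, Cyp1a2 only in Cy5, and Kif1c was higher in the ratio and lower in Cy5.

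The gene lists for xenobiotic sensing were higher in M as groups. Of 18 measured CAR targets, 12 rose (12 when adjusted over the list alone) and none fell, with a median log2 difference of 0.72 (camera adjusted p = 5.57e-08, adjusted p = 0.181 with an estimated correlation). Besides Cyp2b2, Cyp2c7, Ephx1 and Aldh1a1 they included the bile transporter Abcc3, at 0.76 ± 0.11 (at least 1.41-fold by the scaling of the bound, but 1.35-fold in Cy5 alone). Of 9 AhR targets, 4 rose (4 when adjusted over the list alone), namely Cyp1a1, Cyp1b1, Nqo1 at 1.15 ± 0.18 and the glucuronosyltransferase Ugt1a6 at 1.04 ± 0.18, with a list median of 0.16 (camera adjusted p = 0.000101, adjusted p = 0.0587 with an estimated correlation). Of 13 targets of the pregnane X receptor (PXR), 6 rose (6 when adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00848, adjusted p = 0.832 with an estimated correlation). They included the P450 reductase Por at 0.85 ± 0.15, Gstm1 at 0.76 ± 0.14 and Cyp3a23-3a1 at 0.89 ± 0.18, which turned to -0.61 with the scanner software's log ratio. Of 18 Nrf2 targets, 9 rose (10 rose and 2 fell when adjusted over the list alone), with a median of 0.49 (camera adjusted p = 1.9e-06, adjusted p = 0.182 with an estimated correlation). They included the sulfiredoxin Srxn1 at 0.75 ± 0.088 and Sqstm1 at 0.73 ± 0.11, whose other probe gave -0.01. Of 27 glutathione transferases and glucuronosyltransferases, 13 rose (13 when adjusted over the list alone) and none fell, with a median of 0.33 (camera adjusted p = 2.34e-06, adjusted p = 0.35 with an estimated correlation). The largest was Gstm2 at 1.22 ± 0.14, beside Gstm4 at 0.78 ± 0.11 and Gstm3 at 0.62 ± 0.098 (at least 1.41-fold by that scaling, but 1.33-fold in Cy5 alone). These 5 lists share members, and 11 of the 12 CAR, 4 of the 4 AhR, 5 of the 6 PXR, 6 of the 9 Nrf2 and 12 of the 13 conjugation genes that rose were also called higher in Cy5 alone. Fry called 4 lists in this comparison, all of these except the PXR targets. The calls of these 5 lists held when any 1 array was left out, and across all alternatives the adjusted p of the called lists ranged from 3.53e-23 to 0.835.

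Other hepatic enzyme genes, of which Alas1 and Sult1b1 are also CAR targets, differed between M and C. The male-specific steroid hydroxylase Cyp2c11 rose by 1.09 ± 0.21 and the heme synthesis gene Alas1 by 0.93 ± 0.23. The sulfotransferase Sult1b1 rose by 1.08 ± 0.26 and the pericentral ammonium transporter Rhbg by 0.92 ± 0.13. These 4 genes were also called higher in Cy5 alone. The steroid hydroxylase Cyp17a1 was lower at -0.43 ± 0.12, the acute phase inhibitor A2m at -0.85 ± 0.19, the sterol transporter Abcg5 at -0.86 ± 0.26 and the glycolytic Pklr at -0.48 ± 0.11, each also called lower in Cy5 alone. Of 17 periportal genes 4 fell (5 when adjusted over the list alone), with the mitochondrial Aldh1b1 at -0.50 ± 0.091, Sdsl at -0.55 ± 0.14, the glutaminase Gls2 at -0.47 ± 0.13 and Agxt at -0.50 ± 0.16, but the list as a group had a median of -0.21 and no call (camera adjusted p = 0.0644). Of these, Aldh1b1 and Gls2 were also called lower in Cy5 alone. The interferon regulator Irf1 fell by 0.56 on the log2 scale with an SE of 0.13 and was also called lower in Cy5 alone, and Oas1b fell by 0.34 without a call in Cy5 alone. Some of these genes no longer passed with 1 array fewer and kept their direction. Abcg5 was at -0.77, -0.80 and -0.61 without C 10, C 12 or M 5 (adjusted p = 0.0819, 0.071 and 0.0904), and Gls2 at -0.39 and -0.40 without C 9 or M 6 (0.0534 and 0.0521). Agxt was at -0.45, -0.45, -0.37 and -0.50 without C 10, C 12, M 5 or M 6 (0.0935, 0.0866, 0.109 and 0.068), and Cyp17a1 at -0.38 without M 6 (0.05). Cyp2c11 was well above background on only 1 of the 4 C arrays, and over the alternatives its difference ranged from 0.68 to 2.57, called in all of them.

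Cyp1a2, a sentinel AhR target, did not differ in the ratio of M to C (-0.11 ± 0.12, adjusted p = 0.552), although its Cy5 signal was 4.74-fold higher, and its reference signal was higher on slide 2 by 2.39 on the log2 scale. The growth factor Igf1 was lower in the ratio at -0.36 ± 0.10 (adjusted p = 0.0239) and at 0 in Cy5 alone. Without C 11, M 5 or M 7 it no longer passed, at -0.33, -0.32 and -0.34 (adjusted p = 0.0657, 0.0646 and 0.0547). The glucocorticoid sentinels Fkbp5, Tsc22d3 and Tat were at 0.15 ± 0.24, -0.25 ± 0.19 and 0.13 ± 0.26, and Igfbp1 at 0.21 ± 0.32, without a call. The proliferation list was higher in M with a median of 0.20 over 22 genes (camera adjusted p = 0.00363, adjusted p = 0.835 with an estimated correlation), with Birc5 at 0.49 ± 0.11 and Ccnb2 at 0.37 ± 0.092 the 2 members that rose (2 when adjusted over the list alone). Neither was called in Cy5 alone, where they were at 0.17 and 0.03 and the list median was 0.10.

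Of 12072 genes limma called 2459 between M and C, 989 higher and 1470 lower (40.2% higher). In Cy5 alone it called 273, of which 73.3% were higher, and 152 genes were called in the same direction in both. In the reference channel alone, where no pup RNA was present, 66% of genes were called between the slides, against no gene within slide 1 and 1 gene within slide 2. Fitted within an array row, the comparison gave 837 calls in row 1 and 705 in row 2, with a correlation across genes of 0.66 between the rows (genes are not independent replicates), and 3324 calls with row as a block. With array row within each slide as a block, chosen after the row effect was seen, it gave 2459 calls. The genes called were not all the same: of 133 genes named by the rule, 16 lost their call and 5 gained one.

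**Figure D2:**
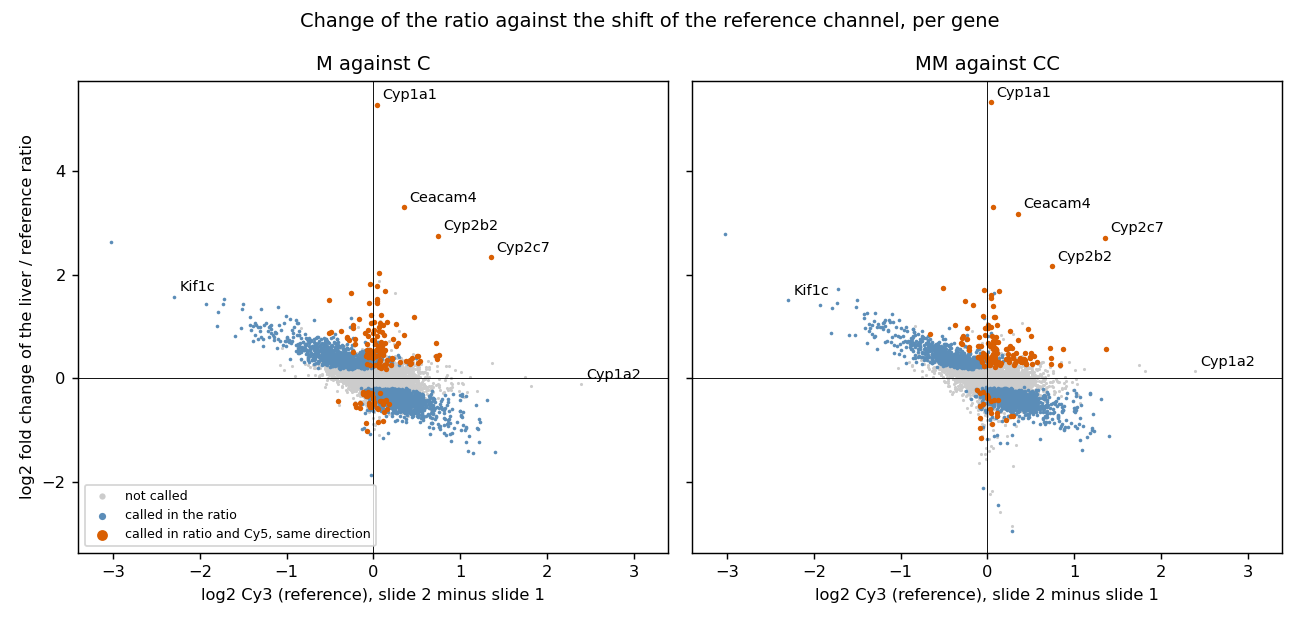
Log2 difference of the liver over reference ratio (y axis) against the log2 difference of the reference signal between slides (x axis, slide 2 minus slide 1), a point per gene, for M against C and MM against CC. Blue points are genes called in the ratio and orange points those also called in Cy5 alone in the same direction, 152 and 154 genes, while many other called genes have a reference shift opposite to their ratio.

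The comparison of MM with CC asks the same question in cross-fostered pups. Cyp1a1 was 40.4-fold higher in MM (log2 5.33 ± 0.27 SE, n = 4 arrays per group, adjusted p = 3e-09), Ceacam4 9.06-fold (3.18 ± 0.12, adjusted p = 5.25e-11), Cyp2c7 6.58-fold (2.72 ± 0.27, adjusted p = 7.83e-06) and Cyp2b2 4.49-fold (2.17 ± 0.20, adjusted p = 4.81e-06). In Cy5 alone they were 20.3-fold, 8.85-fold, 13.8-fold and 7.16-fold higher, beside reference shifts between the slides of 0.04, 0.36, 1.35 and 0.75. Cyp1b1 was higher by 1.74 ± 0.12 (at least 2.21-fold by the scaling of the bound, but 2.09-fold in Cy5 alone), Tsku by 1.70 ± 0.26, Aldh1a1 by 1.69 ± 0.26, Cyp2a3 by 1.56 ± 0.28 (at least 2.31-fold by that scaling, but 2.11-fold in Cy5 alone) and Ephx1 by 1.49 ± 0.17, each also called higher in Cy5 alone. Kif1c was higher by 1.51 ± 0.11 in the ratio and at -0.85 in Cy5 alone. Within array row 1 the log2 differences of Cyp1a1, Ceacam4, Cyp2b2 and Cyp2c7 were 5.53, 3.36, 2.38 and 2.99, and within row 2 they were 5.14, 3.00, 1.95 and 2.44.

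The 10 largest falls in MM included 4 genes of muscle. The troponins Tnnc2 and Tnnt1 were at -2.96 ± 0.88 and -2.13 ± 0.56, the leiomodin Lmod2 at -1.18 ± 0.37 (at least 1.9-fold with all arrays by the scaling of the bound, but 1.58-fold in Cy5 alone) and the myosin light chain Myl4 at -1.10 ± 0.29, and none of these was called in Cy5 alone. Muscle transcripts were high on 2 of the 4 CC arrays, CC 1 and CC 2, and Tnnc2 was at -2.15, -2.14, -2.88 and -3.02 without CC 1, CC 2, MM 2 or MM 4, where it no longer passed (adjusted p = 0.0758, 0.0859, 0.0554 and 0.0501). Lmod2 shrank to -0.82 and -0.85 without CC 1 or CC 2 (0.106 and 0.121). Without any of MM 1 to MM 4 it stayed at -1.13, -1.19, -1.21 and -1.18, and only the adjusted p rose (0.0729, 0.0639, 0.0555 and 0.0709). Tnnc2 was well above background on 3 of the 4 MM arrays, and Lmod2 on 3 of the 4 CC arrays. The other largest falls were Coro1a, a leukocyte actin-binding gene, at -1.18 ± 0.26, Qsox1 at -1.15 ± 0.22, Zc3h13 at -1.14 ± 0.11, Bax at -1.05 ± 0.059, Tmem33 at -0.96 ± 0.074 and the macrophage receptor Marco at -0.93 ± 0.28. Of these only Qsox1 was also called lower in Cy5 alone, at -1.11, although its other probe gave -0.15. Marco was at -0.93, -0.83, -0.90 and -0.74 without CC 1, CC 3, MM 1 or MM 4, where it no longer passed (0.0525, 0.0806, 0.0597 and 0.0956). In Cy5 alone Coro1a was at -0.53 and Marco at -0.56, while Zc3h13, Bax and Tmem33 turned to 0.08, 0.06 and 0.30.

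The same xenobiotic lists were higher in MM. Of 9 AhR targets 4 rose (5 when adjusted over the list alone), with Nqo1 at 1.42 ± 0.18 and Ugt1a6 at 0.96 ± 0.18, a median of 0.27 and a camera adjusted p = 1.64e-05. In the ratio this was the only list call of all comparisons that also passed with an estimated correlation (adjusted p = 0.0461 with an estimated correlation). In Cy5 alone, camera with an estimated correlation called 3 lists in M against C and 3 in MM against CC. Of 18 CAR targets 9 rose (10 rose and 1 fell when adjusted over the list alone), with Por at 0.97 ± 0.15 and a median of 0.50 (camera adjusted p = 1.44e-07, adjusted p = 0.181 with an estimated correlation). Of 13 PXR targets 6 rose (6 rose and 1 fell when adjusted over the list alone), with the canalicular transporter Abcc2 at 0.57 ± 0.11, Cyp3a23-3a1 at 0.80 ± 0.18 and a median of 0.47 (camera adjusted p = 0.00164, adjusted p = 0.606 with an estimated correlation). Of 18 Nrf2 targets 7 rose and 1 fell (8 and 1 when adjusted over the list alone), with Srxn1 at 0.82 ± 0.088, Sqstm1 at 0.62 ± 0.11 and a median of 0.45 (camera adjusted p = 0.000101, adjusted p = 0.407 with an estimated correlation). Of 27 conjugation enzymes 10 rose (13 when adjusted over the list alone), with Gstm2 at 1.18 ± 0.14, Gsta1 at 0.69 ± 0.14, Gstm3 at 0.44 ± 0.098 (at least 1.15-fold, and 1.25-fold in Cy5 alone, well above background on 3 of the 4 MM arrays) and a median of 0.30 (camera adjusted p = 9.36e-05, adjusted p = 0.549 with an estimated correlation). The ribosomal protein control list was lower, with a median of -0.20 over 19 genes and 6 falls (6 when adjusted over the list alone), including Rps3 at -0.33 ± 0.072 and Rplp0 at -0.33 ± 0.08 (camera adjusted p = 0.00358, adjusted p = 0.832 with an estimated correlation). With the series table this list turned upward (adjusted p = 0.878). Fry called all 6 of these lists, each held its call when any 1 array was left out, and across all alternatives their adjusted p ranged from 7.15e-17 to 0.878.

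Other liver genes that differed between MM and CC were the male-specific Cyp2c11, higher by 0.97 ± 0.21, and Rhbg, higher by 0.56 ± 0.13, with A2m lower at -0.89 ± 0.19, Abcg5 at -0.96 ± 0.26 and Aldh1b1 at -0.36 ± 0.091. All 5 were also called in Cy5 alone in the same direction. Abcg5 was at -0.78 without CC 1 and no longer passed (adjusted p = 0.0515). Cyp2c11 was well above background on 1 of the 4 CC arrays and ranged from 0.67 to 2.90 over the alternatives that tested it, called in all of them. The filter on all 16 arrays left it untested. The apolipoprotein Apoa2 was higher by 0.56 ± 0.14, its Cy5 signal by 1.89 and its reference signal on slide 2 by 1.37, and with the scanner software's log ratio it turned to -0.05. The macrophage markers Aif1 and C1qc fell with Marco, at -0.54 ± 0.15 and -0.35 ± 0.12, which made 3 of 16 Kupffer cell genes (3 when adjusted over the list alone), but the list had no call (median -0.24, camera adjusted p = 0.186). None of the 3 was called in Cy5 alone. Aif1 was at -0.46, -0.44 and -0.45 without CC 1, MM 3 or MM 4 and no longer passed (0.0531, 0.0539 and 0.0635), nor did C1qc without any array except MM 2, at -0.37 to -0.22 (0.0576 to 0.108). Cyp1a2 again did not differ in the ratio, at 0.14 ± 0.12 (adjusted p = 0.454), with a Cy5 signal 5.59-fold higher. Fkbp5, Tsc22d3, Tat, Igf1 and Igfbp1 were at -0.14 ± 0.24, -0.28 ± 0.19, -0.43 ± 0.26, -0.10 ± 0.10 and 0.52 ± 0.32, without a call.

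Limma called 2419 genes between MM and CC, 945 higher and 1474 lower (39.1% higher). The share of higher calls depended on the scaling: 52% of 2160 calls were higher with the series table, with median centring 17.6% of 4936 calls, and in Cy5 alone 83.2% of 316 calls. Median centring moved the median of all genes from -0.06 to -0.19. In both the ratio and Cy5 alone, 154 genes were called in the same direction. Fitted within an array row the comparison gave 591 calls in row 1 and 1210 in row 2, with a correlation across genes of 0.54 between the rows, and 3296 calls with row as a block, against 2224 with array row within each slide as a block. With the latter block, of 113 genes named by the rule, 13 lost their call and 5 gained one.

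Across genes, the differences of M from C and of MM from CC correlated at r = 0.78 (rho = 0.74) in the ratio and 0.62 (0.5) in Cy5 alone, and genes are not independent replicates. Both comparisons share the slide difference. They shared 679 genes called higher and 917 called lower, and in Cy5 alone 139 and 28. The interaction asks whether the mixture effect differed between cross-fostered and own-dam pups. Cyp1a1, Cyp2b2 and Nqo1 had interaction terms of 0.05 ± 0.38, -0.59 ± 0.29 and 0.27 ± 0.25, without a call. The smallest p belonged to the myosin Myo1e at 0.72 ± 0.15, the mannosidase Man1a2 at 0.44 ± 0.12, Wwc2 at 0.46, the peroxisomal Pxmp4 at -0.70 ± 0.20, Tm2d1 at -0.54, Epb41l5 at -0.41, Nemf at 0.46, Ldaf1 at 0.37, Nubp1 at -0.38 and Zdhhc1 at 0.35, and none passed (adjusted p = 1). Limma called 0 genes, with 349 at an unadjusted p below 0.05, and 0 in Cy5 alone with 313. The 95% interval lay within 2-fold of no difference for 96.9% of genes. Fitted within array row 1, the interaction gave 19 calls, 18 of them lower. Among these were the muscle genes Myl11 at -5.22 ± 0.28, Tnnc2 at -4.91 ± 0.23, Tnni2 at -4.75 ± 0.18 and Mb at -4.44 ± 0.16. Bdh1 was the 1 higher gene at 1.76 ± 0.18, and all were named after their values were seen. Each group had 2 arrays in this row, and the CC arrays were CC 1 and CC 2. On these, 15 and 11 of 19 adipose and skeletal muscle markers were above 2-fold of the slide median. Within row 1 limma called 24 genes between CC and C, with Myl11 at 5.16, but between MM and M only Bdh1. For the interaction within row 2 limma called 0 genes, with 589 at an unadjusted p below 0.05.

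The comparison of CC with C asks what cross-fostering changed without the mixture. No gene passed, and the largest differences that were named are of transcripts of other tissues. The skeletal muscle troponin Tnnt1 was at 1.87 ± 0.56 SE (n = 4 arrays per group), Tnni2 at 2.31 ± 0.84, Myl11 at 2.54 ± 0.93 and myoglobin Mb at 2.19 ± 0.82. The digestive enzymes Cpb1, Ctrb1 and Cpa1 of the exocrine pancreas were at 1.91 ± 0.72, 2.50 ± 1.1 and 1.69. Among other genes, Irf1 was at -0.53 ± 0.13, Man1a2 at -0.32 ± 0.087, the phosphatase Dusp6 at -0.59 ± 0.17 and Chka at -0.46. Banp, Arhgap28, Cfl2, Hira and Aifm2 were at -0.46, -0.25, 0.31, -0.27 and -0.28. None of these passed (adjusted p = 1). Some were well above background on part of the arrays only: Mb on 2 of 4 C and 3 of 4 CC arrays, Cpa1 on 1 and 2, Cfl2 on 1 and 3, Banp on 4 and 1, and Man1a2 and Arhgap28 on 4 and 3. The sentinels Fkbp5, Tsc22d3, Tat, Igf1 and Igfbp1 were at 0.04 ± 0.24, -0.17 ± 0.19, 0.10 ± 0.26, -0.17 ± 0.10 and -0.43 ± 0.32, and Cyp1a1, Cyp2b2 and Nqo1 at 0.08 ± 0.27, 0.42 ± 0.20 and -0.08 ± 0.18.

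Camera called 9 lists between CC and C, with no called member in any of them. The exocrine pancreas and gut markers were higher with a median of 1.69 over 5 genes (adjusted p = 9.23e-05, adjusted p = 0.407 with an estimated correlation). Proliferation genes were higher with a median of 0.18 (adjusted p = 1.44e-07, adjusted p = 0.791 with an estimated correlation), among them Birc5 at 0.28 ± 0.11 and Plk1 at 0.20. The growth hormone and IGF axis was lower, at -0.12 (adjusted p = 0.00682, adjusted p = 0.181 with an estimated correlation), with Igfals at -0.27 ± 0.12 and Onecut1 at -0.54. These 3 calls held when any 1 array was left out, and the other 6 were lost or turned without a single array. Cholesterol synthesis was higher at 0.31 (adjusted p = 0.00152, adjusted p = 0.835 with an estimated correlation), with Fdps at 0.60 ± 0.45 and Msmo1 at 0.58, and turned downward without C 9 (adjusted p = 0.000718). The acute phase genes, at -0.21, had an adjusted p = 1.99e-05 and adjusted p = 0.832 with an estimated correlation, and lost the call without CC 1 (0.255), with Fgb at -0.63 ± 0.36 and Saa4 at -0.52 ± 0.27. The hepatocyte markers, at -0.23 (adjusted p = 5.64e-05, adjusted p = 0.832 with an estimated correlation), turned without CC 1 (0.748). On CC 1 these markers were low in the ratio but near the slide's median in Cy5 alone. The adipose and skeletal muscle markers had a median of 0.15 and a mean of 1.04 over 7 genes (adjusted p = 0.0106, adjusted p = 0.832 with an estimated correlation), 3 of them higher when adjusted over the list alone, and lost the call without CC 1 (0.568). Gluconeogenesis and glycolysis, at -0.05 (adjusted p = 0.00816, adjusted p = 0.791 with an estimated correlation), lost it without CC 1 or C 10 (0.283 and 0.0841). The interferon response, at -0.10 (adjusted p = 0.00994, adjusted p = 0.835 with an estimated correlation), with 1 member lower when adjusted over the list alone, lost it without CC 1, C 9, CC 2 or C 11 (0.203, 0.149, 0.17 and 0.2). Across all alternatives the adjusted p of the 9 lists ranged from 6.11e-14 to 0.903.

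Transcripts of other tissues were confined to arrays of row 1 when counted as markers above 2-fold of the slide median. Of 17 pancreas and gut markers, 12 were above on CC 2, 9 on MM 1, 8 on CC 1, 6 on M 6 and 1 on M 5. Of 19 adipose and skeletal muscle markers, 15 were above on CC 1, 11 on CC 2 and 3 on C 10, the last being the brown fat genes Ucp1, Cidea and Adipoq. No marker of either list was above on the other arrays. Within row 1 limma called 24 genes between CC and C, with Myl11 at 5.16 ± 0.20, Tnnc2 at 4.89 ± 0.16, Tnni2 at 4.65 ± 0.13 and Mb at 4.36 ± 0.11, named after their values were seen. Within row 2 it called 0, with 314 at an unadjusted p below 0.05, and Myl11 was at -0.09. The list medians in rows 1 and 2 were 3.15 and 0.20 for pancreas and gut, 0.75 and -0.17 for cholesterol synthesis, and -0.54 and 0.08 for hepatocyte markers, and 4 of the 9 called lists had the same sign in both rows.

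**Figure D3:**
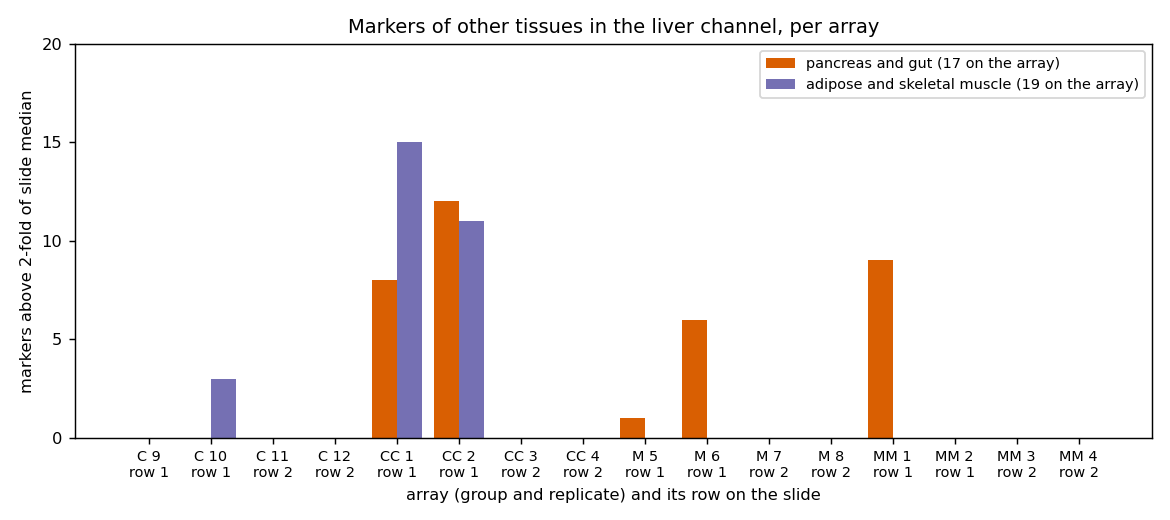
Number of marker genes above 2-fold of the slide median on each array, for 17 pancreas and gut markers and 19 adipose and skeletal muscle markers, with the array row given. The arrays with 5 or more markers of either list, CC 1, CC 2, MM 1 and M 6, are all in row 1.

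Limma called 0 genes between CC and C, with 336 at an unadjusted p below 0.05, and 0 in Cy5 alone with 289. Both numbers are below the share of 0.05 of all 12072 genes that chance alone would give. The 95% interval lay within 2-fold of no change for 98.7% of genes.

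The comparison of MM with M asks what cross-fostering changed in pups exposed to the mixture. The xenobiotic genes did not pass: Cyp1a1 was at 0.13 ± 0.27 SE (n = 4 arrays per group), Cyp1a2 at 0.14, Cyp2b2 at -0.17 ± 0.20, Cyp3a23-3a1 at -0.20 and Nqo1 at 0.19 ± 0.18. The glucocorticoid and growth sentinels Fkbp5, Tsc22d3, Tat, Igf1 and Igfbp1 were at -0.25 ± 0.24, -0.20 ± 0.19, -0.46 ± 0.26, 0.08 ± 0.10 and -0.13 ± 0.32. The smallest p belonged to Myo1e at 0.46 ± 0.11, the selenophosphate synthetase Sephs2 at 0.60 ± 0.15, the lipid droplet gene Ldaf1 at 0.29, the fatty acid transporter Slc27a1 at -0.27, Pyroxd1 at 0.23, Aen at -0.47, Akr1c13 at 0.96 ± 0.28, Isg20l2 at -0.28, Lst1 at -0.43 and Rab40b at 0.23, and none passed (adjusted p = 0.999). Limma called 0 genes, with 275 at an unadjusted p below 0.05, and 0 in Cy5 alone with 262, and the 95% interval lay within 2-fold for 99% of genes.

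Camera called 7 lists between MM and M, again without a called member. Heat shock genes were lower with a median of -0.10 over 16 genes, with the chaperone Hspa8 at -0.56 ± 0.25 (adjusted p = 0.00286, adjusted p = 0.832 with an estimated correlation), and this call held when any 1 array was left out. Kupffer cell genes were lower at -0.16 (adjusted p = 0.000379, adjusted p = 0.832 with an estimated correlation), with Aif1 at -0.37 ± 0.15 and Marco at -0.50, and lost the call without M 8 (0.132). Endothelial genes, at -0.10 (adjusted p = 0.00641, adjusted p = 0.832 with an estimated correlation), with Lyve1 at -0.15, lost it without MM 3 or M 7 (0.46 and 0.185). CAR targets, at -0.14 (adjusted p = 0.00913, adjusted p = 0.832 with an estimated correlation), with Alas1 at -0.47 and Ces2c at -0.34 ± 0.15, lost it without M 5, MM 3 or M 7 (0.0685, 0.234 and 0.0719). PPARa targets, at -0.09 (adjusted p = 0.0196, adjusted p = 0.835 with an estimated correlation), with Cyp4a3 at -0.33, lost it without MM 3, M 7, MM 4 or M 8 (0.386, 0.335, 0.0602 and 0.308). Periportal genes were higher at 0.11 (adjusted p = 0.00948, adjusted p = 0.832 with an estimated correlation), with Aldh1b1 at 0.18, and lost it without M 5, MM 1, M 6 or MM 4 (0.0642, 0.164, 0.121 and 0.179). Ribosomal protein genes, at -0.05 (adjusted p = 0.0122, adjusted p = 0.835 with an estimated correlation), lost it without M 6, MM 3 or MM 4 (0.207, 0.0581 and 0.0975). Across all alternatives the adjusted p of the 7 lists ranged from 1.38e-07 to 0.867, and 4 of the 7 had the same sign in both array rows. Within row 1 limma called 1 gene, the ketone body dehydrogenase Bdh1, at 1.61 ± 0.12 (adjusted p = 0.0151), which was at -0.81 in row 2, and this gene was named after its values were seen. Within row 2 limma called 0 genes, with 741 at an unadjusted p below 0.05.

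Averaged over exposure, cross-fostering gave Rab40b at 0.21 ± 0.05 SE, Irf1 at -0.31 ± 0.09, Hspa8 at -0.45 ± 0.18, Cyp2c7 at -0.46 ± 0.19, Hmgcs1 at 0.49 and A2m at 0.31, with Fkbp5, Tat and Igfbp1 at -0.10, -0.18 and -0.28. The other genes with the smallest p were Lgalsl at -0.24, the Wnt receptor Fzd1 at 0.27, Casp8ap2 at -0.17, Sephs2 at 0.36, B3galt1 at -0.44, Parp9 at -0.22, Emp2 at 0.18 and Hira at -0.18, and none passed (adjusted p = 1). Limma called 0 genes, with 250 at an unadjusted p below 0.05, and 0 in Cy5 alone with 219, and the 95% interval lay within 2-fold for 99.5% of genes. Within array row 1 the averaged effect gave 17 calls, all higher. Among them were the muscle genes Myl11 at 2.56 ± 0.14, Tnnc2 at 2.43 ± 0.12 and Tnni2 at 2.28 ± 0.089, named after their values were seen. Each group had 2 arrays in that row, and its CC arrays were CC 1 and CC 2, on which muscle transcripts were high. Within row 2 limma called 0 genes, with 418 at an unadjusted p below 0.05. Across genes, the differences of CC from C and of MM from M correlated at r = -0.06 (rho = -0.14).

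Camera called 12 lists for the averaged effect, of which 0 held with an estimated correlation and 3 kept the call when any 1 array was left out. These 3 were the interferon response, lower at -0.09 (adjusted p = 0.00044, adjusted p = 0.832 with an estimated correlation), proliferation, higher at 0.09 (adjusted p = 1.99e-05, adjusted p = 0.832 with an estimated correlation), and pancreas and gut markers, higher at 0.85 (adjusted p = 0.00132, adjusted p = 0.606 with an estimated correlation). Without CC 1 the call was lost for CAR targets (median -0.10), PPARa targets (-0.09), fatty acid synthesis (0.13), acute phase (-0.12) and adipose and muscle markers (0.17), at adjusted p = 0.369, 0.163, 0.0625, 0.419 and 0.59, and the hepatocyte markers (-0.09) turned (0.184). With all arrays the adjusted p of these lists were 0.00682, 0.00177, 0.026, 0.000379, 0.039 and 0.00682, and adjusted p = 0.832, 0.832, 0.835, 0.832, 0.832 and 0.835 with an estimated correlation. Without MM 3 it was lost for CAR targets, PPARa targets, fatty acid synthesis, hepatocyte, Kupffer cell (-0.08) and adipose and muscle markers (0.0981, 0.082, 0.0537, 0.143, 0.0581 and 0.0994). Cholesterol synthesis, at 0.25 (adjusted p = 5.64e-05, adjusted p = 0.835 with an estimated correlation), lost it without C 9 (0.957). Heat shock genes, at -0.07 (adjusted p = 0.00251, adjusted p = 0.832 with an estimated correlation), lost it without CC 3 or CC 4 (0.0736 and 0.0629), and Kupffer cell genes (adjusted p = 0.00192, adjusted p = 0.832 with an estimated correlation) without M 8 (0.105). PPARa targets lost it without M 7 as well (0.0612). Fatty acid synthesis lost it also without C 9, CC 2, M 5, MM 1, MM 2, M 7 or M 8 (0.713, 0.103, 0.149, 0.0954, 0.0825, 0.101 and 0.0619), and adipose and muscle markers without CC 2, C 11, C 12, M 5, MM 1, M 6 or M 7 (0.0915, 0.0612, 0.0899, 0.097, 0.145, 0.0511 and 0.101). Across all alternatives the adjusted p of the 12 lists ranged from 2.51e-10 to 0.957. Of the 12 lists, 10 had the same sign in both array rows.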

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

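The tests of the 3 patterns weighed first were chosen after the result was seen, as were the fits within each array row, the row blocks within slides and the fits that leave out several arrays, while the comparison of each array with its group, the interaction and the counts over other splits of the arrays were planned.

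Most genes called between the mixture and control groups had a reference channel that moved too. In M against C 73.7% of the called genes, and in MM against CC 76.7%, had a Cy3 difference between the slides that opposed the ratio and was larger than their Cy5 difference. That fits a reference that differed between slides. The ratio is built from both channels, so a larger Cy3 difference nearly fixes the opposite sign. This share was not counted over all genes, where Cy3 differences also had the larger SD (0.276 and 0.275, against 0.194 and 0.205 in Cy5). Cy3 alone, without any pup RNA, called 66% and 66.4% of all genes between the same arrays. A slide difference common to both dyes would cancel in the ratio. This share therefore does not decide whether the mixture acting on the liver accounts for every call. Of 100 genes called in Cy5 alone but not in the ratio in M against C, 99 had a reference shift in the same direction. In MM against CC these were 133 of 134. A Cy5 difference without a ratio difference nearly requires such a shift, so these 2 counts decide nothing. Over all genes the Cy5 and Cy3 differences correlated at 0.3 in M against C and 0.33 in MM against CC. Calls in Cy5 alone may therefore still carry part of the slide difference. Members of the 5 xenobiotic lists were called in both the ratio and Cy5 at odds 63.9 and 38.2 times those of other genes. These were 28 of 70 and 21 of 70 members against 124 and 133 of 12002 (Fisher's exact p = 8.47e-36 and 9.29e-24). Genes are not independent replicates, so these p-values do not measure the spread between arrays. In the ratio, camera with an estimated correlation passed only for the AhR targets in MM against CC. An effect of the mixture on those genes would give such odds. A slide difference in the liver channel could not be separated from it by design.

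Pancreas and muscle transcripts appeared on single arrays. On 3 of the 8 cross-fostered arrays and 1 of the 8 own-dam arrays, all in row 1, 5 or more pancreas markers were above 2-fold. With 1 own-dam array among them, cross-fostering as the source is neither shown nor excluded. Where the trypsinogen Prss1 was above 2-fold, at least 5 other pancreas and gut markers were too, so pancreas tissue in some of the pooled liver samples is a candidate explanation. The bounds of both tests were set after the marker counts had been seen. For the muscle and brown fat transcripts on CC 1, CC 2 and C 10 the same kind of source was not tested by itself.

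The array row on slide 2 separated the arrays in a way that the groups do not explain, with 2 M and 2 MM arrays in each row. Between the rows 1876 genes were called in the ratio and 2024 in Cy5 alone, and 4 in Cy3 alone (992 at an unadjusted p below 0.05). The row differences had an SD across genes of 0.0565 in Cy3 and 0.212 in Cy5. A position effect that acts on both dyes alike is excluded as the whole source by the count in Cy3, and a smaller one is not. Liver RNA collected, extracted or labelled in sets that match the rows and a biological difference between the pups of the 2 sets (litter, for example) would each give the 2024 genes in Cy5, so that count does not decide between them and both stay open. On slide 1 the counts were 1 in the ratio (2059 at an unadjusted p below 0.05), 7 in Cy5 and 0 in Cy3 (1352 at an unadjusted p below 0.05) by limma.

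For the interaction camera called 7 gene lists at its preset correlation, of which 0 held with an estimated correlation (adjusted p = 0.832 to 0.835) and 0 kept the call when every array was left out in turn. The hepatocyte markers (adjusted p = 0.00322, median 0.36), acute phase genes (0.0106, median 0.25), periportal genes (0.00848, median 0.16) and gluconeogenesis and glycolysis (0.0211, median 0.11) were higher, and pancreas and gut markers (0.0179, median -1.67), proliferation (0.00175, median -0.15) and ribosomal protein genes (0.00994, median -0.10) were lower. Without CC 1 the call was lost for hepatocyte (0.485), acute phase (0.561), periportal (0.184), gluconeogenesis (0.126) and pancreas genes (0.0912). Proliferation lost it without M 5 (0.0712), and ribosomal proteins without CC 2, C 12 or M 6 (0.121, 0.0924 and 0.0903). Acute phase genes lost it also without C 12 or MM 4 (0.127 and 0.126), gluconeogenesis without C 10, MM 1, M 6 or MM 4 (0.0908, 0.106, 0.154 and 0.119), periportal genes without MM 1, M 6 or MM 4 (0.0961, 0.0561 and 0.0602) and pancreas genes without CC 2, MM 3 or MM 4 (0.0685, 0.0794 and 0.0576). Across all alternatives the adjusted p of the 7 lists ranged from 2.92e-07 to 0.898. The 7 calls were matched or exceeded in 55 of 100 shuffles within slides, the highest with 20, so chance cannot be excluded.

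Single arrays stood far from the other 3 of their group in 57 of 843 tests of named genes, where chance alone gives about 1 in 20, or 42, and in 7 of 84 tests of lists, where it gives 4. The value given is the gap to the nearest array divided by the range of the group, in the log2 ratio. CC 1 was singled out 22 times. Among others, it was lowest for the liver genes Cyp27a1 (0.967), Ttr (0.952), Fbp1 (0.942), Apoc3 (0.934), Apoa1 (0.934), Slc13a3 (0.929), Saa4 (0.906), Itih3 (0.895), Fgb (0.88), Abcb4 (0.869), Apoa2 (0.86), Igf1 (0.854) and Man1a2 (0.836), and for the hepatocyte markers (0.937) and PXR targets (0.907) as lists. It was highest for Hira (0.944), Coro1a (0.923), Sult1b1 (0.889), Fabp4 (0.865), Cd79b (0.839) and the adipose and muscle list (0.895). As a deviation of the list median in the log2 ratio from the slide's median, the hepatocyte list was at -1.04 on CC 1 and at 0 to 0.07 on the other CC arrays, while in Cy5 alone it was at -0.07 on CC 1. The low hepatocyte list on CC 1 was thus hardly seen in the liver channel. The reference channel of CC 1 stood apart, with 1.32% of values over 0.5 on the log2 scale from the slide's median, against 0.01% to 0.11% on the other arrays. In Cy5 this share was 5.9% on CC 1 and 5.7% on MM 3. Over its 7 tested genes the adipose and muscle list was at 2.07 on CC 1 and at -0.12 to 0.11 on the other CC arrays. Over all 19 markers, dim ones included, the median deviation was 2.12 on CC 1 and 1.95 on CC 2, so CC 1 did not stand alone for these transcripts.

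C 9 was singled out 7 times, lowest for Thra (0.937), Psd (0.866) and Banp (0.838) and highest for Cyp4a3 (0.85), Cpt2 (0.844), Gpt (0.838) and Ahcy (0.831). M 6 was lowest for Fbp1 (0.963), Hal (0.927) and Ccnb2 (0.9) and highest for Cpb1 (0.866) and for the pancreas and gut (0.944) and acute phase lists (0.938). MM 1 was lowest for Hsph1 (0.969) and highest for Ctrb1 (0.941), Cpa1 (0.885), Sgk1 (0.835) and the pancreas and gut list (0.883). MM 3 was lowest for Cyp4a1 (0.926), Rpl7 (0.832), Fgb (0.83) and the conjugation enzymes as a list (0.833), and highest for Rpl30 (0.861). C 11 was highest for Cpa1 (0.915) and Hmox1 (0.882) and lowest for Nemf (0.85) and Gstm2 (0.848).

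Among the remaining arrays, MM 2 was lowest for Fabp4 (0.922) and Irs2 (0.86) and highest for Hmox1 (0.868), CC 4 lowest for Cdkn1a (0.877) and highest for Akr1c1 (0.865), and M 7 lowest for Cyp1a1 (0.909) and Rabgap1 (0.879). M 8 was lowest for Hsf1 (0.934) and highest for Emp2 (0.842), and MM 4 was lowest for Rplp0 (0.937) and Cd79b (0.854). Single values came from C 10, lowest for Cyp2c7 (0.854), CC 2 for Gapdh (0.843), CC 3 for Por (0.89) and M 5 for Abcg5 (0.891). No explanation was tested for the arrays of these last groups of genes.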

How the results depend on the processing

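The tests with calls in both channels, with array row within each slide as a block, with several arrays left out and within each array row were chosen after the results were seen, and the others were planned. Calls between the mixture and control groups were found under every setting, and their number changed. For M against C the count of 2459 became 4024 with the scanner software's log ratio, 273 in Cy5 alone, 420 with a fold of at least 1.5, 152 with a call in both, and 1358 without M 6 and C 9. Leaving out 1 array gave 1895 (without M 6) to 2151 (without M 7). For MM against CC the count of 2419 became 3957 with the scanner software's log ratio, 4936 with median centring, 316 in Cy5 alone, 1547 with only the groups compared, 393 with a fold of at least 1.5, 154 with a call in both and 1177 without CC 1, CC 2 and MM 1. Leaving out 1 array gave 1764 (without CC 2) to 2219 (without MM 3). The replicate number as a block, fitted to the CC and MM arrays only, gave 2000, against the 1547 of those groups without the block. In both groups replicates 1 and 2 lay in array row 1 and replicates 3 and 4 in row 2, so this block includes the array row. The lower counts with fewer arrays come with fewer samples and those with a fold or a double call with a stricter rule, and for the others the cause was not tested.

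Limma called 0 genes in both cross-fostering comparisons, the interaction and the averaged effect under every setting fitted to both array rows together and without any 1 array, with 186 to 1034 genes at an unadjusted p below 0.05. In the main fit these numbers were 336, 275, 349 and 250. Each is below the share of 0.05 of 12072 genes that chance alone would give. With array row as a block they were 508, 473, 632 and 384, and with the scanner software's log ratio 737, 549, 697 and 558. Of these, 632, 737 and 697 are above that share. The lowest number in the range, 186, was of 9802 genes well above background on all 16 arrays. The highest, 1034, was of 26913 genes without the filter on dim probes. Within row 1 alone limma called 24 (CC against C), 1 (MM against M), 19 (interaction) and 17 (averaged effect), and within row 2 alone 0 in each (314, 741, 589 and 418 at an unadjusted p below 0.05). Of the 47 list calls 1 passed with an estimated correlation (14 of 228 at an unadjusted p below 0.05) and 10 with fry, and the other settings gave 32 to 56. The cause was not tested.

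Cy5 alone reversed some named genes. In M against C these were Kif1c (-0.79), Tmem33 (0.18), Bax (0.12), Tubgcp3 (0.09), Cdkn1a (0.06), Thra (-0.05), Mthfd1 (-0.14), Pfkl (0.44), Hmox1 (-0.10), Id1 (0.01), Fcrla (0.04), Reln (-0.03), Epcam (-0.09), Ppib (0.14) and Cyp1a2 (2.24). In MM against CC they were Kif1c (-0.85), Zc3h13 (0.08), Bax (0.06), Tmem33 (0.30), Cdkn1a (0.19), Thra (-0.10), Stip1 (-0.08), Hmox1 (-0.15), Gulo (-0.02), Fcrla (0.03), Tbp (0.06) and Ppib (0.13). Cy5 alone leaves out the reference, whose signal differed between the slides for these genes. The scanner software's log ratio reversed Cyp3a23-3a1 (-0.61) and Bhmt2 (-0.04) in M against C and Apoa2 (-0.05) in MM against CC, and the cause was not tested.

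Single arrays reversed 3 list calls. Cholesterol synthesis in CC against C turned without C 9 (adjusted p = 0.000718, and 3.92e-10 to 0.0225 over the 8 arrays), and the hepatocyte markers turned without CC 1 in CC against C (0.748, and 1.69e-07 to 0.748) and in the averaged effect (0.184, and 0.000135 to 0.184). Without CC 1, CC 2, MM 1, M 6 and C 9 together, the calls kept were 2 of 9 (CC against C), 2 of 7 (MM against M), 3 of 7 (interaction), 2 of 12 (averaged effect), 6 of 6 (M against C) and 5 of 6 (MM against CC). Lists turned in CC against C (cholesterol synthesis 5.7e-11, interferon response 0.117, hepatocyte 0.82, adipose and muscle 0.142), in the interaction (gluconeogenesis 0.781, periportal 0.668) and in the averaged effect (interferon response 0.533, hepatocyte 0.724, adipose and muscle 0.101). The series table turned the ribosomal protein list of MM against CC (0.878), and the cause was not tested. Cy5 was well above background at 46.2% to 53.9% of spots per array, so genes with weaker liver signal were not tested.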

Other observations

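The tests within each array row and of the row blocks were chosen after the result was seen, and the counts over other splits of the arrays were planned. Further genes were called in both the ratio and Cy5 alone, and those named here were chosen after their values were seen. In M against C the aflatoxin reductase Akr7a3 was higher by 1.45 in the ratio and 1.55 in Cy5, the glucuronosyltransferase Ugt2b1 by 1.04 and 1.29, the glutathione transferases Gsta5, Gsta3 and Gsta1 by 0.84 and 1.29, 0.87 and 0.85, and 0.74 and 0.76, Cyp3a62 by 1.22 and 0.79, the carboxylesterase Ces1f by 0.83 and 0.91 and the electron donor Cyb5a by 0.68 and 0.95. The activin gene Inhba was at -0.66 and -0.55. In MM against CC the urinary protein gene Rup2 was higher by 3.32 and 2.49 and the kinase anchor Akap5 by 1.18 and 1.16, and the carnitine acetyltransferase Crat was at -0.77 and -0.84.

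The cholesterol synthesis genes were low on C 9, with a list median at -1.56 in the log2 ratio from the slide's median and -1.54 in Cy5 alone, while the other arrays of slide 1 were at -0.19 to 0.34 in the ratio. Interferon, acute phase and glucose genes had no list call in either mixture comparison: in M against C the interferon response had a median of -0.11 (camera adjusted p = 0.51), the acute phase -0.13 (0.92) and gluconeogenesis and glycolysis -0.16 (0.267). In MM against CC they were at -0.13 (0.623), 0.14 (0.186) and -0.05 (0.933). The PPARa targets in M against C had a median of -0.10 and a mean of -0.07 while the camera test pointed up (0.933), and the bile acid genes a median of -0.07 and a mean of -0.11 while it pointed up (0.92).

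Other splits of the same arrays were counted for each result. For M against C, 1 of 35 splits, the real one, gave as many as the 2459 called genes, and the highest other gave 0. For MM against CC it was 1 of 35, with 2419 genes against 3. The real split is also the split between slides. Every other split puts arrays of both slides into each group, so the slide difference enters the spread within groups and lowers those counts. With 35 splits the real one can also be no rarer than 1 of 35. These counts therefore do not exclude chance for the mixture. For CC against C (0 genes, the highest other 1), 35 of 35 splits gave as many. For MM against M (0 genes) it was also 35 of 35, and the highest other, with 1294 genes, was the split between array rows on slide 2. For the interaction (0 genes, the highest other 152) and the averaged effect (0 genes, the highest other 1873) all 100 shuffles gave as many, and the highest followed the array row on slide 2. With a real count of 0 every split gives as many, so these 4 counts decide nothing about chance, and the large counts point to a structure of the arrays by row. Limma called 0 genes in the 4 also with array row within each slide as a block (509, 479, 639 and 395 at an unadjusted p below 0.05).

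For the number of lists called, chance cannot be excluded in any comparison. The number does not say which lists were called, so it decides nothing about a single list. For M against C and MM against CC every other split again mixes the slides. As many were called in 30 of 35 splits for CC against C (9 lists, the highest other 17), 10 of 35 for MM against M (7 and 11), 27 of 35 for M against C (6 and 14), 27 of 35 for MM against CC (6 and 20), 55 of 100 for the interaction (7 and 20) and 23 of 100 for the averaged effect (12 and 20). All 6 called lists of M against C and all 6 of MM against CC had the same median sign in both array rows. For M against C the medians in rows 1 and 2 were 0.65 and 0.81 for CAR targets, 0.11 and 0.26 for AhR targets and 0.54 and 0.31 for Nrf2 targets.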
